A study of Homo sapiens with 28 samples.

How the data were processed

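Chromatin accessibility was measured by ATAC-seq in Kuramochi, an established BRCA2-mutant ovarian cancer cell line, after adaptation to or exposure to the PARP inhibitor olaparib. Per the labels, libraries were made with the Omni-ATAC protocol from about 50000 cells each and sequenced paired-end on an Illumina NextSeq instrument. The labels list 28 samples. The 20 samples of the untreated population (C), the 7 adapted populations (T5 to T320, named after their dose in uM) and the cells exposed for 9 days (P10 and P320) have a column in the table used here, with 2 replicates per group. The other 8 samples, T320 cells with or without drug, 4 of them after 120 drug-free days, have no column in that table and were not analysed here, so the 5 planned peak comparisons of those samples were not run.

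The deposited table holds counts per consensus peak, which the authors describe as read counts; the values are whole numbers with no normalization. Whether reads or fragments were counted, and how duplicates were handled, is not stated. Trim Galore, Bowtie2, Picard, SAMtools, MACS2, HOMER 4.1, deepTools 3.1 and 3.5.1 and DESeq2 are named per the labels, without their roles, with the build GRCh38. Whether peak starts are counted from 0 is not stated, and they are given as they stand in the table. Total counts per library lay between 9627970 and 29699950. Intervals and errors cover counting and the spread between the libraries of a group. The labels do not say whether replicates were separate cultures.

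Peaks were placed with RefSeq gene positions. The annotation at hand gives no strand, so the promoter of the original plan was replaced by a gene-end peak, a peak within 1 kb of either end of a protein-coding gene. A peak named after a gene may therefore lie at its start or at its far end. Of the 105048 peaks, 15325 were gene-end peaks of 14859 genes, and 81994 lay over 1 kb from the ends of all annotated genes and are called distal. For the gene lists each gene was represented by its gene-end peak with the highest mean count.

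Counts were fitted with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, R 4.3.3) over the 10 groups, without a replicate block. filterByExpr by group removed 0 peaks. A peak was called gained or lost at a Benjamini-Hochberg adjusted p under 0.05 and a log2 fold change of at least 1 in absolute value. CPM are the counts of edgeR's cpm function with TMM-scaled library sizes, given as mean ± SD over n = 2 libraries; log2 fold changes are given with the standard error of the fit. The dose trend was fitted to the counts of the 7 adapted populations, summed over replicates, against log2 of the dose, with no filter, and called at an absolute slope of at least 0.25 log2 units per doubling. The calling rules, the comparisons, the named-gene rule, the gene lists and most alternatives were fixed before the data were examined.

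The 22 gene lists were mesenchymal; epithelial; Mullerian and serous ovarian lineage; AP-1 and immediate early; integrated stress and unfolded protein response; NRF2 and detoxification; ABC transporters; homologous recombination and PARP; p53 targets; interferon response; antigen presentation; NF-kB and inflammatory cytokines; cell cycle; cholesterol and fatty acid synthesis; glycolysis and hypoxia; Wnt and stemness; YAP and TEAD targets; constitutive promoters; and markers of blood, endothelial, hepatocyte and neural cells. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 22 lists within each comparison, and with fry. The lists were planned for T320 against C, P320 against C, T320 against P320 and the trend, and added for T5 against C, P10 against C and P320 against P10 after the data were seen.

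Genes were named by rule. In the 3 main comparisons and the trend these were the 6 largest rises and the 6 largest falls among called gene-end peaks with at least 2 CPM in the higher group and no overlap between the groups' libraries; the 2 members of each list with the smallest adjusted p among those called; CD24, CD44, BRCA2, PARP1, ABCB1 and SLFN11 in any case; and the 3 gained and 3 lost distal peaks with the smallest p, with the nearest gene within 50 kb. Other comparisons gave 3 and 3 gene-end peaks. ABCB1 had no gene-end peak. Some genes that these rules name are not reported here. Other called members of a list are named only to show which they were, and any exception is marked as chosen after its values were seen.

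Alternatives were total-count scaling, TMM from gene-end peaks alone, a trended offset (cyclic loess on mean count), a window offset that removes the median shift of each 5 Mb window as a proxy for DNA copy number, a replicate block, DESeq2 1.42.0, a strict filter (at least 2 CPM in 2 libraries, 104557 peaks), no filter, no fold minimum, a fit of the compared groups alone, and leaving out each library. Where a group kept 1 library it was assumed to vary like the other groups. Lists were also tested over all peaks nearest to each gene. Chosen after the data were seen were the window offset with the replicate block, a filter for the trend, omissions of libraries in the overlap, the contrast of adapted with acute dose effects, gene-end scaling in the overlap, named peaks and list members, and the scan of consecutive peaks. Motif content and GC correction were planned but not run, since they need a genome sequence.

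Replicates with the same number were checked for a shared effect: the difference between replicates 1 and 2, correlated across peaks, had r from 0.17 to 0.59 over the 28 pairs of C and T groups and from -0.10 to -0.01 over the 16 pairs of these with P groups. A replicate block was therefore tried as an alternative. The pipeline was tested on simulated data made from these libraries. With a 4-fold change 46 of 50 changed peaks were found, with a 3-fold change 33 of 50, with a 2-fold change 8 of 50, and 2 of 104848 unchanged peaks were called. For the dose trend, 84 of 100 peaks with a slope of 0.25 and 13 of 104848 unchanged peaks passed on adjusted p. A simulation at other depths was added after the data were seen. For a simulated doubling of chromosome 20, 1073 of its 2990 peaks were called without the window offset and 0 with it.

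Since P320 and T320 were each compared with the same 2 C libraries, the correlation and covariance of their log2 fold changes were set against 8 simulations in which both groups were unchanged. Calls in those simulations numbered at most 2, too few for a reference for the overlap of calls. Dose orders were permuted 40 times for the trend, with the reverse of the real order left out of the draw. Figures were drawn with matplotlib. The R packages data.table, in version 1.17.8, and statmod, in version 1.5.0, were also used.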

Results

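Accessibility was measured in 20 libraries of Kuramochi cells, 2 for each of 10 populations. C was untreated. T5, T10, T20, T40, T80, T160 and T320 had adapted to olaparib at the dose in uM that their names give and were kept at that dose. P10 and P320 were drug-naive cells exposed for 9 days to 10 and 320 uM, called persister cells in the labels. C and the T populations were sorted on CD24 and CD44, the T populations for low CD24 and high CD44. No sort is named for P10 and P320. Where P is compared with T or C, sort can therefore not be told apart from adaptation or exposure. The same holds for T against C as far as C was sorted otherwise. Total counts in peaks ran from 9627970 in T40 replicate 1 to 29699950 in P320 replicate 1, with C at 11347046 and 22218981 and T320 at 10831843 and 23602303. The 105048 peaks had a median width of 1119 bp. Gene-end peaks held 38.2% and 37.5% of the counts in the 2 P320 libraries and between 27.8% and 35.3% in the other libraries.

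The comparison of T320 with C addresses what chromatin differs in cells adapted to the highest dose. Peaks of genes of the Mullerian and serous ovarian lineage fell in T320. Of 15 measured members 0 were gained, 8 were lost and 7 did not pass the test, and the list as a whole fell (adjusted p = 1.9e-07; adjusted p = 0.050 with an estimated correlation). MSLN, which encodes the ovarian tumour antigen mesothelin, went from 51.1 ± 14.3 CPM (SD, n = 2) in C to 10.2 ± 1.1 CPM in T320, a log2 fold change of -2.34 ± 0.25. WT1, a transcription factor used as a marker of serous carcinoma, changed by -1.46, MECOM by -1.03 and EMX2 by -1.01, and SOX17, KLK8, CAPS and BCAM were also lost. The peak of BCAM, a laminin receptor, changed by -1.64 and was no longer called with the window offset, with which 7 members were lost.

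Epithelial genes fell as a list as well (adjusted p = 0.0012; adjusted p = 0.050 with an estimated correlation). Of 25 members 6 were lost, 1 was gained and 18 did not pass. SPINT2, an inhibitor of serine proteases, changed by -1.76 ± 0.24, from 21.1 ± 3.6 to 6.38 ± 2.24 CPM, and CLDN3, ESRP1, ELF3 and MUC1 were also lost. The gain was KRT18, an epithelial keratin, at 1.36. With the window offset 3 members were lost. The call of the list was lost over all peaks nearest to its genes (adjusted p = 0.21) and without T320 replicate 2 (adjusted p = 0.058).

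**Figure D1:**
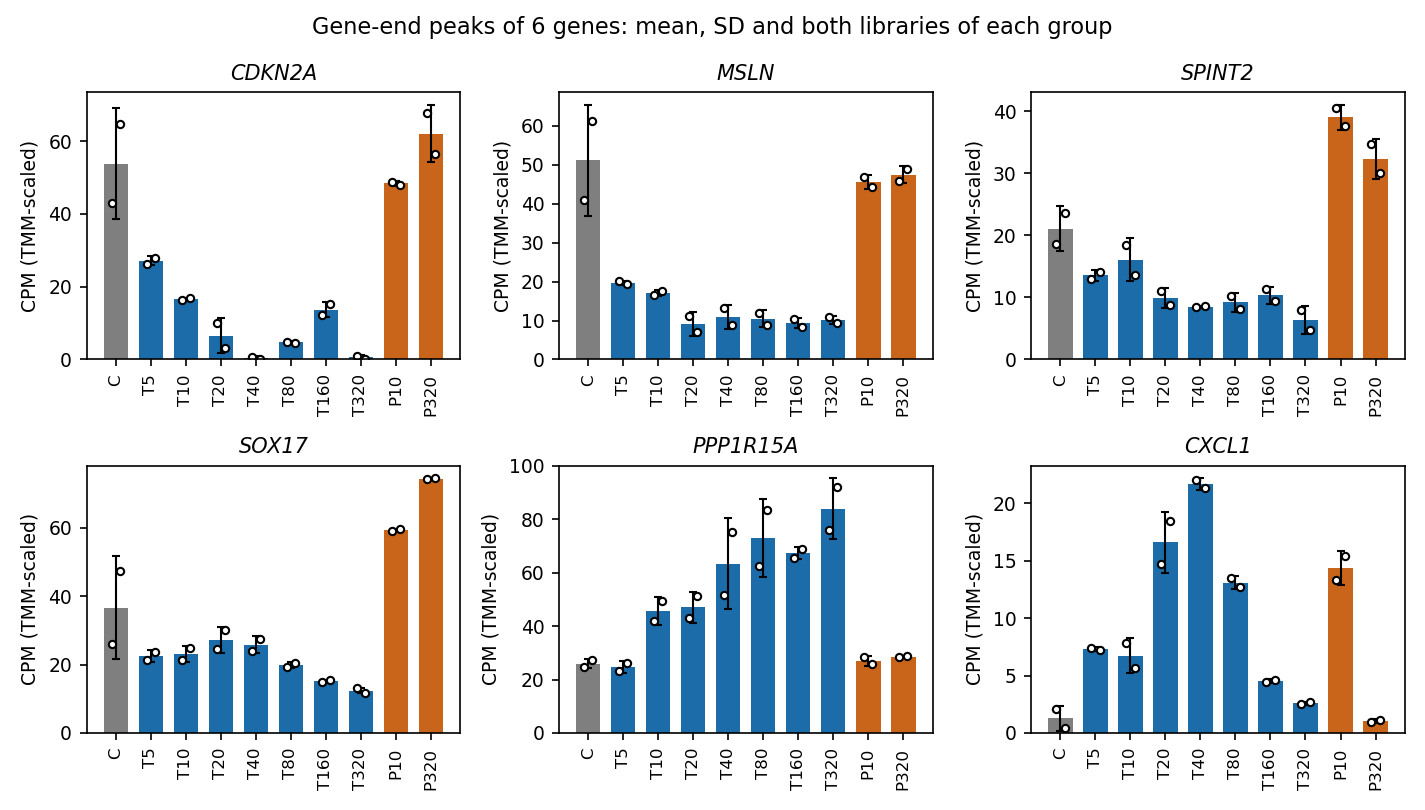
Peak accessibility (y axis, CPM, separate scale per panel) of CDKN2A, MSLN, SPINT2, SOX17, PPP1R15A and CXCL1 in the 10 populations (x axis), with points for both libraries and the mean with SD. MSLN and SPINT2 were at 51.1 and 21.1 CPM in C and at 10.2 and 6.38 CPM in T320, and PPP1R15A was at 25.9 CPM in C and 83.9 CPM in T320.

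None of the other 20 lists passed in T320 against C. Over all peaks nearest to their genes, the mesenchymal (0.0032), NRF2 (0.0075), neural (0.028) and antigen presentation (0.037) lists passed upward. Members of stress and metabolic lists were gained without a call of the list. In the integrated stress and unfolded protein response (adjusted p = 0.094) 3 of 20 were gained: TRIB3, SLC3A2 and PPP1R15A, the phosphatase subunit that restores translation after stress, which rose by 1.70 ± 0.21 from 25.9 ± 1.7 to 83.9 ± 11.4 CPM. In the glycolysis and hypoxia list (0.61) PFKFB4, a regulator of glycolysis whose peak is shared with COL7A1 and UCN2, rose by 2.72 ± 0.31 and was the single gain among 18. Among AP-1 and immediate early genes (0.26) 1 of 21 was gained, KLF6 at 1.85 ± 0.30. ABCG1, a sterol exporter, was the gain among 12 ABC transporters (0.80), at 1.71 ± 0.34. Wnt and stemness genes (0.37) had 1 gain of 16, the Wnt antagonist DKK1. NRF2 and detoxification genes (0.42) had 1 gain of 22, AKR1C2, which was not called with the window offset. SLC3A2 had 0.81 without C replicate 2 or T320 replicate 2, and AKR1C2 had 0.68 without C replicate 2 and 1.16 and 0.94 without T320 replicates 1 and 2, none called. Scaled on gene-end peaks SLC3A2 (0.96) and AKR1C2 (0.98) were not called. With the window offset the integrated stress list passed (0.012). Without C replicate 1 KLF6 had 2.51 and PFKFB4 3.41.

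Lists for immunity and the cell cycle gave few calls in T320. Antigen presentation (adjusted p = 0.37) had 2 gains of 16, HLA-B and HLA-F; HLA-B rose by 1.55 ± 0.45. The interferon list (0.42) had 1 gain of 26, OAS2, and NF-kB and inflammatory cytokines (0.80) 1 of 19, the chemokine CCL20. The p53 targets (0.82) had 2 gains of 18, BAX and GDF15. The single losses were E2F2 among 30 cell cycle genes (0.92) and LATS2 among 17 YAP and TEAD targets (0.82). Cholesterol and fatty acid synthesis (0.80) had 1 gain, SCD, and 1 loss of 22. HLA-F, OAS2, GDF15, E2F2 and LATS2 were not called with the window offset. Calls also ended without T320 replicate 2 for CCL20 (0.73), BAX (0.86), GDF15 (0.46), SCD (0.92) and E2F2 (-0.91), without T320 replicate 1 for OAS2 (0.81) and LATS2 (-0.90), without C replicate 1 for HLA-F (0.93) and BAX (0.89), and without C replicate 2 for HLA-B (1.00), OAS2 (0.63) and GDF15 (1.00), and when scaled on gene-end peaks for HLA-B (1.48), OAS2 (0.96) and GDF15 (0.99). HLA-B had 2.27 without C replicate 1. The test pointed down while median and mean were above 0 for p53 targets, NF-kB and YAP targets, and for ABC transporters the mean alone was above 0.

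In homologous recombination and PARP (adjusted p = 0.72) 1 of 34 was gained, SLFN11, a helicase that stalls stressed replication, at 1.49 ± 0.41; it was not called without C replicate 2 (1.42) or T320 replicate 2 (1.07). PARP1, the target of olaparib, had -0.77 and BRCA2, whose peak is shared with ZAR1L, -0.41, neither called, and PARP1 had 0.02 with the window offset and -1.07, called, without T320 replicate 2. CD24 had -0.04 and CD44 0.88, not called; CD44 was called with the window offset (1.34) and without T320 replicate 1 (1.095), and CD24 had 0.26 without C replicate 2. Mesenchymal genes (0.31) had 4 gains of 31, among them VIM, FN1 and COL5A1. COL5A1 was not called without T320 replicate 2 (0.98).

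Markers of other cell types were measured in the same way. Blood cell markers (adjusted p = 0.33) had 4 gains, CSF1R, ITGAM, ITGB2 and GATA1, and 1 loss, RUNX3, of 7 measured, and ITGB2, an integrin of leukocytes, went from 8.02 ± 2.01 to 25.4 ± 3.2 CPM. Neural markers (0.052) had 3 gains of 8, SYT1, SNAP25 and OLIG2, endothelial markers (0.61) 2 losses of 9, VWF and TIE1, and hepatocyte markers (0.079) 1 loss of 3, APOA1 at -3.15 ± 0.43. Constitutive genes (0.28) had 1 gain of 14, GAPDH. TIE1, RUNX3 and SNAP25 were not called with the window offset, nor were ITGAM (0.87) and SNAP25 (0.92) without T320 replicate 2 or GAPDH without C replicate 1 (0.96). The peak of VWF, T320 against C, was not called without T320 replicate 2 (-1.499). The blood list passed with the window offset (0.037), hepatocyte markers with it (0.014) and without C replicate 2 (0.019) or T320 replicate 1 (0.00037), and neural markers without T320 replicate 2 (0.040). APOA1 had -4.21 and -2.39 without T320 replicates 1 and 2. Adjusted over the list alone, the counts equalled those over all peaks in every list but neural markers, which then had 3 gains and 1 loss.

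The largest falls at gene ends in T320 were at CDKN2A and CDKN2B, neighbouring inhibitors of the cell cycle on chromosome 9. CDKN2A (21993963 to 21997043, GRCh38) went from 53.9 ± 15.3 to 0.56 ± 0.54 CPM, a log2 fold change of -6.86 ± 0.54 (adjusted p = 1.9e-07), and CDKN2B (22008262 to 22009728) from 46.6 ± 19.3 to 0.69 ± 0.60 CPM, -6.31 ± 0.51. HERC6, MTX2, CTPS1, which makes CTP, and PRSS2 followed, at -4.01, -3.90, -3.86 and -3.86. The largest rises were at LOC124904962 (3.78), ANXA5, an annexin (3.77 ± 0.53), a peak near DKK1 that starts at 52318176 on chromosome 10 (3.72 ± 0.51), LOC124901868 (3.68), SMIM21 (3.68) and ERVV-1 (3.67). Without T320 replicates 1 and 2 the values were -8.18 and -5.83 for CDKN2A, -7.41 and -5.39 for CDKN2B, -4.63 and -3.40 for HERC6 and -4.72 and -3.17 for CTPS1. PRSS2 had -4.57 and -3.27 without T320 replicates 1 and 2, MTX2 -3.25 without C replicate 2, ERVV-1 5.22 and 2.73 without C replicates 1 and 2, and the peak near DKK1 4.34 without C replicate 1. Among distal peaks the smallest p belonged to a gain near ZNF665 on chromosome 19 (53181526 to 53183744), from 2.27 ± 1.1 to 63.9 ± 7.6 CPM.

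Over all peaks, edgeR called 32013 between T320 and C, 15714 gained and 16299 lost, and 44240 passed on adjusted p alone. Distal peaks were called more often than gene-end peaks, 33.8% against 12.9%. With the window offset 13587 were gained and 13572 lost, and 22380 of the original calls kept their direction; without C replicate 1 17033 were gained and 16153 lost, without C replicate 2 13300 and 12596, and without T320 replicate 2 11429 and 11129.

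**Figure D2:**
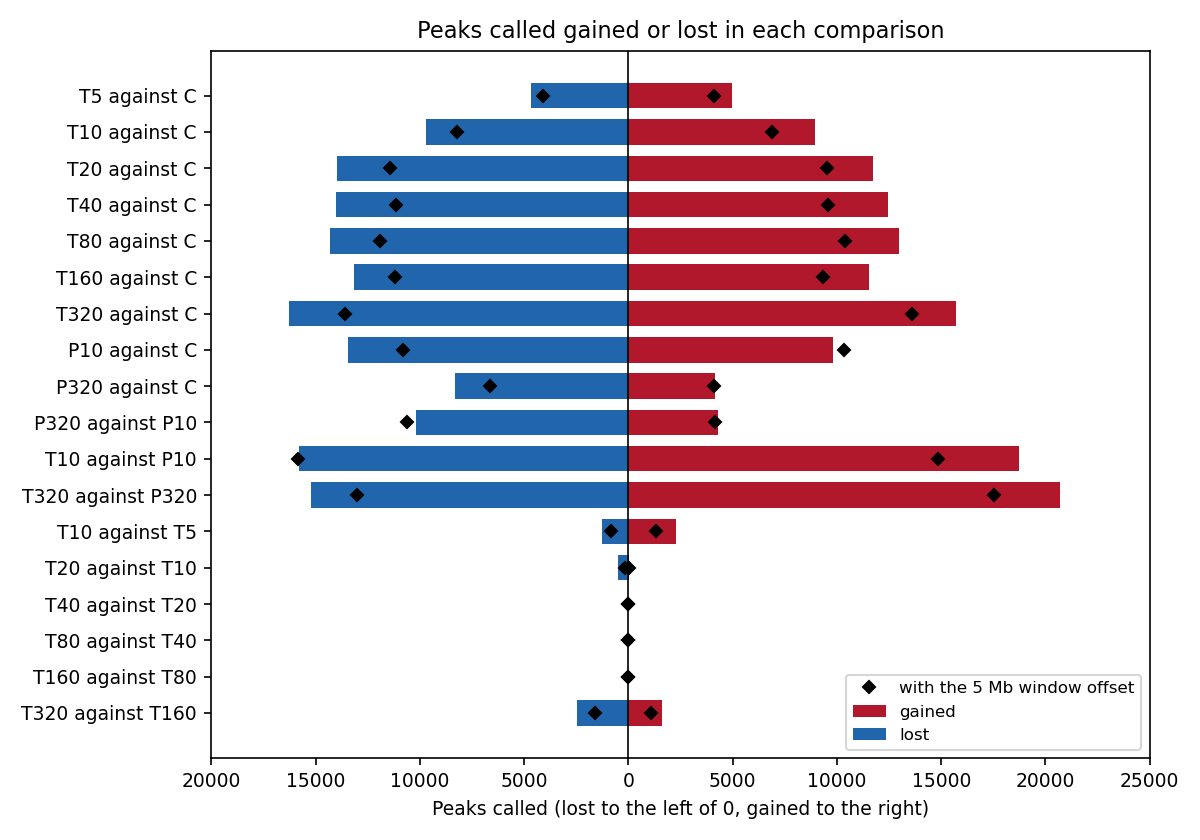
Number of peaks gained (right of 0) and lost (left of 0) on the x axis in each comparison (y axis), at adjusted p under 0.05 and a log2 fold change of at least 1. Comparisons with C, of T with P, of P320 with P10 and between neighbouring doses are drawn. Diamonds give the numbers with the window offset. Against C, gains and losses were 4969 and 4683 in T5, 15714 and 16299 in T320, and 4139 and 8308 in P320.

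The comparisons of T5 to T160 with C address how far each step of adaptation had moved. In T5 a peak at the end of CXCL1, a chemokine that attracts neutrophils (chromosome 4, 73871923 to 73873187), rose by 2.69 ± 0.37, from 1.26 ± 1.12 to 7.30 ± 0.15 CPM. MTX2 and CRYGC were among the falls, at -3.64 ± 0.57 and -3.52 ± 0.56. This CXCL1 peak was at 16.6 CPM in T20, 21.7 CPM in T40 (4.26 ± 0.37) and 13.1 CPM in T80, and at 4.54 CPM in T160 and 2.59 CPM in T320. The zinc-finger genes ZNF66 and ZNF85 on chromosome 19 rose in T10, at 3.07 ± 0.29 and 2.98 ± 0.34, and in T160, at 3.47 and 3.30. TUSC3 rose in T40, T80 and T160, at 3.46, 3.98 and 3.48, and PHLDA1, a regulator of cell death, in T80 at 3.82 ± 0.35. CDKN2B fell in T20 by 3.51 and in T40 by 7.21, and CDKN2A in T40 by 6.99. Falls also included PRSS2 in T10 (-3.25) and CTPS1 in T20 and T80 (-3.46 and -3.80). At OR2T2 different peaks fell, that starting at 248445433 in T80 (-4.37) and that starting at 248444592 in T160 (-4.85). Without C replicates 1 and 2 CXCL1 had 3.93 and 1.83 in T5 and 5.50 and 3.40 in T40, and without C replicate 2 MTX2 had -2.99 in T5 and ZNF85 3.66 in T10 and 3.98 in T160. PRSS2 had -4.24 and -2.59 without T10 replicates 1 and 2, OR2T2 -8.77 and -3.71 without T160 replicates 1 and 2, CDKN2A -8.00 and -6.06 without T40 replicates 1 and 2, CDKN2B -6.53 without T40 replicate 2 and -4.27 in T20 without T20 replicate 1, and TUSC3 2.80 without T40 replicate 2.

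Lists were tested in T5 alone of these, and none passed (smallest adjusted p = 0.065, shared by mesenchymal up, epithelial down and lineage down), but the epithelial list passed with the window offset (0.036). MSLN was the lineage member lost, FN1 was among the mesenchymal gains, and 0 of 25 epithelial members passed with edgeR. Gains and losses were 4969 and 4683 in T5, 8944 and 9688 in T10, 11742 and 13973 in T20, 12425 and 14017 in T40, 12967 and 14314 in T80 and 11530 and 13169 in T160. Scaling on gene-end peaks changed the share gained from 51.5% to 66.4% in T5, from 45.7% to 35.5% in T20, from 47.0% to 34.8% in T40 and from 47.5% to 36.4% in T80. Which side held more peaks turned under at least 1 choice in each of these. In T5 losses led with the window offset (4080 gained and 4086 lost), that offset with the block (5028 and 6224), the block (6087 and 7149), the trended offset (5106 and 5585) and only the groups compared (4149 and 5044). Gains led with no fold minimum in T10, T40, T80 and T160, and also without any 1 of the C and T10 libraries in T10 (10236 and 9044 without C replicate 1), without T20 replicate 2 in T20 (8006 and 7993), without C replicate 1, C replicate 2 or their own replicate 2 in T40 (14051 and 13669 without C replicate 1) and T80 (14469 and 13935), and without C replicate 1 in T160 (12941 and 12476). The T5 total of 9652 was 4186 without C replicate 2, 6124 without T5 replicate 1 and 2831 without T5 replicate 2; that of T10 was 10005 without T10 replicate 2, and that of T20 15999 without T20 replicate 2.

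Steps between neighbouring doses gave fewer calls. From T5 to T10, BCHE rose by 2.87 ± 0.43 and TLR4, a receptor of innate immunity, by 2.46 ± 0.31, and 2264 peaks were gained and 1259 lost. From T10 to T20, CDKN2B fell from 16.3 to 4.25 CPM (-1.99 ± 0.39) and SMYD3 by 2.07, and 46 peaks were gained and 524 lost. From T20 to T40, T40 to T80 and T80 to T160, edgeR called 0 peaks, with 5906, 4180 and 8113 at an unadjusted p under 0.05. With no change at all, a share of 0.05 of the 105048 peaks would pass that cut. The 4180 lie below that share and the 5906 not far above it. DESeq2 called 42, 8 and 143 peaks, and with a replicate block the counts were 7, 0 and 161. From T160 to T320, CDKN2A fell by 4.88 ± 0.55, CDKN2B by 4.35 ± 0.52 and REC8, a meiotic cohesin, by 2.46 ± 0.30, while ZNF492 rose by 2.28, and 1600 peaks were gained and 2454 lost.

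The step counts rested on single libraries and on scaling. T10 against T5, 3523 peaks, gave 2010 without T5 replicate 1, 412 without T5 replicate 2, 706 without T10 replicate 2 and 5798 with the replicate block; 64.3% were gained, or 35.7% when scaled on gene-end peaks. For T20 against T10, 570 peaks, the counts were 129 and 12 without T10 replicates 1 and 2 and 2 without T20 replicate 2, and 8.07% were gained, or 18.8% of 1710 with the replicate block and 19.6% with DESeq2. SMYD3 and CDKN2B were not called there without T20 replicate 2 (-1.86 and -1.42) or T10 replicate 2 (-1.91 and -1.92), nor SMYD3 with the window offset. The peak of CDKN2B, T20 against T10, was also not called without T10 replicate 1 (-2.042). T320 against T160, 4054 peaks, gave 2693 and 281 without T160 replicates 1 and 2, 393 without T320 replicate 2 and 6447 with the block, with 39.5% gained, or 52.5% when scaled on gene-end peaks. ZNF492 was not called there without T160 replicate 1 (2.33), T160 replicate 2 (2.22) or T320 replicate 2 (2.24). Without T320 replicates 1 and 2 CDKN2A had -6.21 and -3.85 and CDKN2B -5.45 and -3.43, and without T320 replicate 1 REC8 had -3.10; in T20 against T10 CDKN2B had -2.74 without T20 replicate 1.

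A position along the line from C (0) to T320 (1), from the peaks called in T320, was given to each library. Means were 0.33 ± 0.03 in T5, 0.57 ± 0.04 in T10, 0.71 ± 0.11 in T20, 0.77 ± 0.12 in T40, 0.80 ± 0.11 in T80 and 0.74 ± 0.03 in T160 (SD, n = 2). P10 was at 0.31 and P320 at 0.11. Simulated unchanged groups, drawn with the spread fitted over all groups rather than that of C, lay between 0.048 and 0.049. On the gained peaks alone P320 was at -0.03, and on the lost peaks alone at 0.26.

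**Figure D3:**
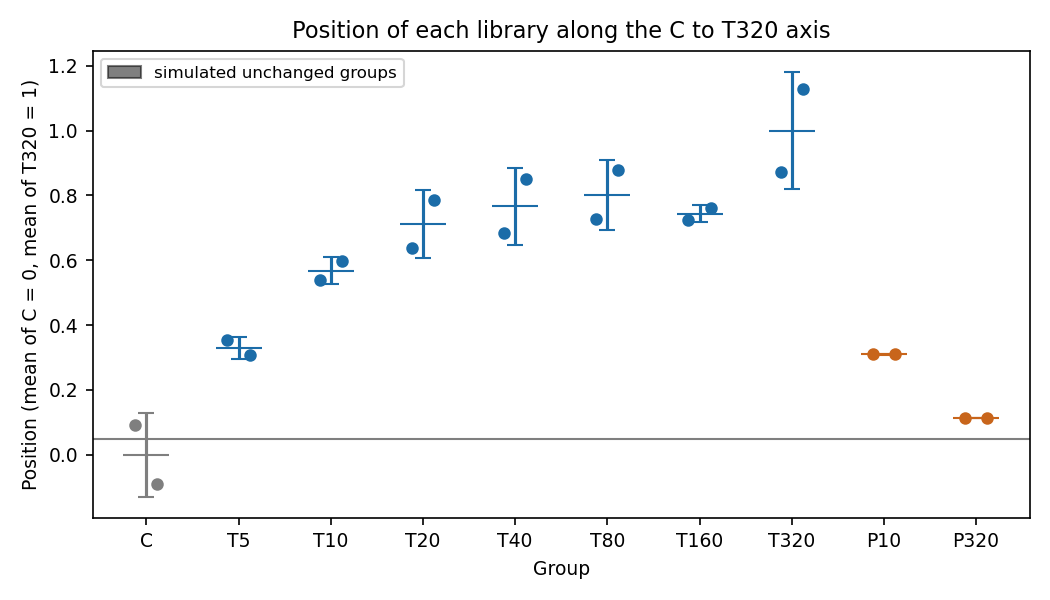
Position of each library (points, 2 per population) along the line from the mean of C, set to 0, to the mean of T320, set to 1 (y axis, no unit), from mean log2 CPM of peaks gained minus peaks lost in T320; the line marks simulated unchanged groups. T80 averaged 0.80, P10 0.31 and P320 0.11.

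The trend over the 7 adapted populations asks which peaks followed the dose. A peak shared by DDIT3, the stress transcription factor CHOP, and MARS1 rose by 0.53 ± 0.07 log2 units per doubling, from 6.02 ± 2.21 CPM in T5 to 28.1 ± 6.8 CPM in T320. Which end of DDIT3 or MARS1 it marks was not determined, so it need not be the promoter of either gene. Other rises were at ARRDC3 (0.49 ± 0.04), GAS6, a ligand of the AXL receptor (0.53 ± 0.06), TMEM156 (0.54) and SMIM21 (0.57). FBXO47 fell with a slope of -0.63 ± 0.09, and HPCAL1 and ATG9B, an autophagy gene, with -0.49 and -0.45; HPCAL1 was not called without T5 (-0.32). In all, 3535 peaks rose and 2470 fell, and 3178 and 1854 of these were also gained and lost in T320 against C. The total of 6005 was 3806 without replicate 2, 9154 without T160 and 1673 without T320. Without T320 more fell than rose, 1033 against 640, and without T5 2953 rose and 1129 fell.

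By list, the trend was down for the lineage genes (adjusted p = 2.7e-05; adjusted p = 0.17 with an estimated correlation), of which 0 of 15 passed alone with edgeR, and for hepatocyte markers (0.0023; adjusted p = 0.17 with an estimated correlation), where 1 of 3, APOA1, fell. It was up for AP-1 and integrated stress genes (both 0.0023; adjusted p = 0.48 and adjusted p = 0.62 with an estimated correlation). KLF6, at 0.30 ± 0.05, was the AP-1 member that rose, and 2 members rose adjusted over the list alone; 0 of 20 stress genes passed. Glycolysis genes and constitutive genes were up (both 0.033; both adjusted p = 0.69 with an estimated correlation), with PFKFB4 rising by 0.36 ± 0.04 and 0 of 14 constitutive genes called, and neural markers were up (0.045; adjusted p = 0.48 with an estimated correlation), with OLIG2 rising. The other 15 lists did not pass (smallest adjusted p = 0.066, interferon response, or 0.027 without T10). With the window offset the interferon (0.026) and epithelial (0.040) lists passed downward and the neural call ended (0.065).

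Several of these trend calls rested on part of the libraries or on the choice of peaks. Over all peaks nearest to their genes the integrated stress (0.21), hepatocyte (0.13), neural (0.080) and constitutive (0.13) calls ended, and the NRF2 (0.0060) and antigen presentation (0.040) lists passed upward. Without replicate 2 the adjusted p was 0.064 for the AP-1 list, 0.15 for glycolysis, 0.15 for hepatocyte markers, 0.096 for neural markers and 0.064 for constitutive genes. The glycolysis call also ended without T5 (0.073), T20 (0.057) or T320 (0.096), the constitutive call without T5 (0.27), and the neural call without replicate 1 (0.066), T10 (0.084), T20 (0.057), T160 (0.059) or T320 (0.076). KLF6, APOA1 and OLIG2 were not called with the window offset, nor without replicate 2 (0.21, -0.17 and 0.20) or T320 (0.25, -0.21 and 0.26). APOA1 was also not called without T5 (-0.25), nor OLIG2 without replicate 1 (0.28), T5 (0.18), T10 (0.26) or T80 (0.25).

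The comparison of P320 with C addresses a first exposure to the highest dose. Peaks at the ends of CCNE1, FASN and LATS2 were among those that rose. CCNE1, the cyclin that starts DNA replication, rose by 1.65 ± 0.21, from 16.2 ± 0.2 to 50.8 ± 1.0 CPM (SD, n = 2), FASN, which makes fatty acids, by 1.48 ± 0.18, and LATS2, a kinase of the Hippo pathway, by 1.47 ± 0.18. With scaling on gene-end peaks, an alternative added for named peaks after the data were seen, CCNE1 was still called, while FASN (0.99) and LATS2 (0.98) were not. The largest rises included TRAF3 at 2.64 ± 0.39, the amino acid transporter SLC7A5 at 2.56 ± 0.34, the phosphatase PTPRM at 2.46 ± 0.23 and AGAP1 at 2.43 ± 0.22. EGR1, an immediate early transcription factor, fell by 1.33 ± 0.17, from 175.5 ± 10.4 to 69.9 ± 0.7 CPM, and FAM240A and RGS4 fell by 2.60 and 2.32, RGS4 by 1.73 without C replicate 1.

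None of the 22 lists passed in P320 against C; the smallest adjusted p was 0.11, for the interferon list, of which 1 of 26 was gained, RSAD2, not called without C replicate 2 (0.78). Without C replicate 2 the interferon and NF-kB lists and the hepatocyte, blood and endothelial markers ranked below the other gene-end peaks. Gene-end peaks had a median of 0.38 in the main fit, so a low rank is not a fall of the members. Medians there were 0.07 for interferon, 0.22 for NF-kB, 0.03 for blood, 0.15 for endothelial and -0.61 for hepatocyte genes. Over all peaks nearest to their genes the NRF2 (0.00041), AP-1 (0.0023), cholesterol and fatty acid (0.0064) and p53 (0.019) lists passed, all upward. Glycolysis and hypoxia genes had 6 gains of 18 (0.38), among them BNIP3 at 1.91 ± 0.24. The AP-1 list had 5 gains and 1 loss of 21 (0.47), or 6 gains and 1 loss adjusted over the list alone, with KLF2 at 2.27 ± 0.26. Integrated stress genes had 4 gains of 20 (0.59), including ERN1, a sensor of unfolded proteins, at 1.47 ± 0.21, and NRF2 genes 4 of 22 (0.25), including SRXN1 at 1.34 ± 0.21. There were 4 gains of 16 Wnt genes (0.35; NKD1 at 1.90), 4 of 17 YAP and TEAD targets (0.25; CRIM1 at 1.68), 3 of 22 cholesterol and fatty acid genes (0.25; ACSL1 at 2.03) and 3 of 12 ABC transporters (0.61; ABCA3 at 1.69 and ABCC4 at 1.31). Mesenchymal genes had 3 gains of 31 (0.59), epithelial genes 3 of 25 (0.56; GRHL1 at 1.83) and p53 targets 3 of 18 (0.59). These counts depended on scaling: on gene-end peaks the gains were 1 in glycolysis, 2 in AP-1, 0 in integrated stress, NRF2 and p53, 1 in Wnt, ABC transporters, cholesterol, mesenchymal and epithelial, and 2 in YAP and TEAD, and ERN1 (0.99), SRXN1 (0.83), ABCC4 (0.81) and RSAD2 (0.70) were not called.

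In the lineage list 1 of 15 was gained and 1 lost in P320 (0.25). SOX17, a Mullerian transcription factor, rose by 1.01 ± 0.21, from 36.7 ± 15.1 to 74.4 ± 0.1 CPM, and KLK8 had -1.07. SOX17 was not called with total-count scaling, the trended or window offset, or without C replicate 1 (0.65), nor KLK8 without P320 replicate 2 (-0.99). Homologous recombination and PARP had 2 gains of 34 (0.35), EZH2, a histone methyltransferase, at 1.39 ± 0.19, and XRCC3, not called with 3 other scalings or without C replicate 1 (0.65). Cell cycle had 2 gains of 30 (0.65), NF-kB genes 1 gain and 1 loss of 19 (0.25), and antigen presentation (0.47) and constitutive genes (0.47) 0 calls of 16 and 14 with edgeR. Blood markers had 1 gain of 7 (0.35), endothelial 2 of 9 (0.25; 2 gains and 1 loss adjusted over the list alone), neural 2 of 8 (0.55; CHGA at 1.66) and hepatocyte 0 of 3 (0.25). In the remaining lists the count adjusted over the list alone was the same. CD44 rose by 1.18 ± 0.23, and had 0.97 with the trended offset. CD24 had 0.98, PARP1 0.96, SLFN11 0.26 and BRCA2 0.05, none called. CD24 was called with the window offset and DESeq2 and without C replicate 2 (1.28), P320 replicate 1 (1.04) or P320 replicate 2 (1.02), and PARP1 without C replicate 2 (1.18) or P320 replicate 2 (1.103); BRCA2 had -0.14 without C replicate 1. Scaled on gene-end peaks, SOX17 (0.56), EZH2 (0.90), XRCC3 (0.56) and CD44 (0.68) were not called, and the lineage list had 0 gains and 2 losses. With that scaling endothelial markers had 1 gain and 3 losses, NF-kB genes 0 and 2, and interferon genes 0 and 3.

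In P320, 4139 peaks were gained and 8308 lost. Without P320 replicate 1 the numbers were 3423 and 3088, without P320 replicate 2 3524 and 3040, so that gains outnumbered losses, and in a fit of only the groups compared 5462 and 6102. Gene-end peaks were gained 2140 times and lost 169 times, distal peaks 1698 and 7657 times, with median log2 fold changes of 0.38 and -0.22. Scaling on gene-end peaks lowered the median of all peaks by 0.49 log2 units and gave 826 gained and 23427 lost, so that the share gained went from 33.3% to 3.41%. The total of 12447 was 6511 and 6564 without either P320 library and 19961 with no fold minimum.

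The comparison of P10 with C addresses a first exposure to a lower dose, and that of P320 with P10 the effect of dose at 9 days. The CXCL1 peak rose in P10 by 3.67 ± 0.37, to 14.4 ± 1.5 CPM from 1.26 ± 1.12 CPM, and was at 1.04 ± 0.17 CPM in P320, a fall from P10 of -3.79 ± 0.35. CXCL2, a related chemokine, was at 7.74 ± 0.71 CPM in P10 and 0.35 ± 0.09 CPM in P320 (-4.46 ± 0.56). A gene-end peak of SHLD1, a subunit of the shieldin complex that limits resection of DNA ends, fell from 5.62 ± 0.67 to 0.15 ± 0.11 CPM (-5.21 ± 0.70). Which end of SHLD1 this peak marks was not determined, so it need not be the promoter. CAND1 rose by 3.15 ± 0.35 and SMYD2 from 3.37 ± 0.90 to 27.0 ± 0.2 CPM. In P10 against C FAM240A fell by 2.83 ± 0.44. CXCL1 had 4.91 and 2.81 in P10 without C replicates 1 and 2, and SHLD1 -4.61 and -6.18 without P320 replicates 1 and 2.

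By list, camera ranked 7 lists below the other gene-end peaks in P320 against P10, where gene-end peaks had a median of 0.33, so that a low rank is not a fall of the members. NF-kB and inflammatory cytokines (adjusted p = 1.2e-11; adjusted p = 0.057 with an estimated correlation) had CXCL8, CCL20, IL1B and BIRC3 lost of 19 and a median of -0.09. Blood cell markers (9.1e-07; adjusted p = 0.034 with an estimated correlation) had CSF1R and ITGB2 lost of 7 and a median of -0.46, and endothelial markers (6.5e-05; adjusted p = 0.057 with an estimated correlation) ROBO4 lost of 9 and a median of -0.37. Interferon genes (6.5e-05; adjusted p = 0.59 with an estimated correlation) had OAS1, OAS2 and TRIM22 lost of 26, a median of 0.00 and a fry adjusted p of 0.80. Antigen presentation (0.0073; adjusted p = 0.59 with an estimated correlation) had HLA-B lost of 16, a median of 0.18 and a fry adjusted p of 0.98. Hepatocyte markers (0.050; adjusted p = 0.59 with an estimated correlation) and mesenchymal genes (0.030; adjusted p = 0.97 with an estimated correlation) had 0 members called by edgeR, and the mesenchymal median and mean were above 0, at 0.04 and 0.10. In P10 against C no list passed (smallest adjusted p = 0.10, NF-kB, with CXCL1, CXCL2, CCL20 and IL1B gained), and with the window offset the NF-kB list passed upward (0.0068). In P320 against P10 the mesenchymal and hepatocyte calls ended with that offset (0.060 and 0.066).

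For P10 against C 9789 peaks were gained and 13428 lost, 42.2% gained, or 26.6% when scaled on gene-end peaks. Gains outnumbered losses in a fit of only the groups compared (12225 and 11638) and with window offset and block (12340 and 11643). The total of 23217 was 12799 without C replicate 2 and 15416 without P10 replicate 2. P320 against P10 gave 4303 gained and 10168 lost, 29.7% gained, or 9.25% when scaled on gene-end peaks. Its total of 14471 was 7729 and 7384 without P10 replicates 1 and 2 and 5725 and 6884 without P320 replicates 1 and 2.

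The comparison of T320 with P320 sets adapted against newly exposed cells at the same dose. T320 was sorted for low CD24 and high CD44 and no sort is named for P320, so sort and adaptation cannot be told apart. Lineage genes were lower in T320 as a list (adjusted p = 0.023; adjusted p = 0.63 with an estimated correlation; 0.092 without T320 replicate 2), with 7 of 15 lost. SOX17 was at 12.4 ± 0.8 CPM in T320 and 74.4 ± 0.1 CPM in P320 (-2.59 ± 0.23), and WT1, MECOM, MSLN, BCAM, HOXA10 and CAPS were the other losses. Of 25 epithelial genes 10 were lost, though the list did not pass (0.097, or 0.012 without T320 replicate 1 and 0.035 over all peaks nearest to its genes), with SPINT2 at -2.38 ± 0.24. PPP1R15A was higher in T320 by 1.55 ± 0.20, PFKFB4 by 2.20 ± 0.29 and EGR1 by 1.71 ± 0.17, and the peak near DKK1 by 5.29 ± 0.55. CDKN2A and CDKN2B were lower, at -7.06 ± 0.54 and -6.33 ± 0.51, and CCNE1 at -2.09 ± 0.21. Without T320 replicates 1 and 2 CDKN2A had -8.39 and -6.03 and CDKN2B -7.43 and -5.40. Scaled on gene-end peaks, the lineage losses were 5 and the epithelial losses 5. Of all 15325 gene-end peaks 3102 were lost and 696 gained in T320 against P320, with a median log2 fold change of -0.40.

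The other 20 lists did not pass in T320 against P320 (smallest adjusted p = 0.17, blood cell markers), and mesenchymal genes passed upward over all peaks nearest to them (0.027). Losses were 7 of 17 YAP and TEAD targets, with LATS2 at -2.52 ± 0.18, 7 of 22 cholesterol and fatty acid genes, with FASN at -1.60 ± 0.18, and 6 of 22 NRF2 genes, or 2, 4 and 0 when scaled on gene-end peaks. With 3102 of 15325 gene-end peaks lost in this comparison, such counts are not particular to the lists. PARP1 fell by 1.74 ± 0.22 and had -0.90, not called, with the window offset. The peak of CD24, T320 against P320, had -1.02, and -0.9501 with total-count scaling and -0.99 without T320 replicate 2 and -0.57 scaled on gene-end peaks, none called. BCAM was not called with the window offset, with which the blood cell markers passed (0.0097). SLFN11 had 1.24, and 0.81 and 0.92, not called, without replicate 2 of T320 or P320. For the mesenchymal, AP-1, integrated stress, repair, interferon, NF-kB, cell cycle, Wnt and endothelial lists the test pointed up while median and mean lay below 0. Counts adjusted over the list alone equalled those over all peaks.

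In T320 against P320 20693 peaks were gained and 15232 lost, 57.6% gained, or 83.5% when scaled on gene-end peaks, which raised the median by 0.44. T10 against P10 gave 18746 gained and 15822 lost, a total of 34568 that was 22799 without T10 replicate 2. With the window offset losses outnumbered gains, 15830 against 14831, as with window offset and block, 18055 against 14973. SLC35F1 was higher in T10 by 3.87 ± 0.38 and PDZK1IP1 lower, at -3.94 ± 0.46 (2.94 ± 0.79 against 44.1 ± 3.3 CPM). SLC35F1 had 4.61 without P10 replicate 1.

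The overlap of P320 against C with T320 against C asks whether a first exposure and adaptation changed the same peaks. KLF6, TRIB3, KRT18, DKK1 and GATA1 were the list members gained in both, and KLK8 was lost in both, while SOX17 and LATS2 were gained in P320 and lost in T320. For DKK1 this is its list peak, not the peak near DKK1 that starts at 52318176. The latter differed more between T320 and P320 than between T320 and C, so it was not gained in P320. Calls that ended under alternatives included those of TRIB3, KRT18, GATA1, KLK8, SOX17 and LATS2 in P320 and of LATS2 in T320. Of all peaks 957 were gained in both, against 619 for independent lists, 2351 were lost in both, against 1289, and 1384 were called in opposite directions. The 2 lists are not independent, since both rest on the same C libraries, which can push calls the same way. The numbers for independent lists are therefore no fair reference, and an excess of shared calls was not shown. The log2 fold changes had r = 0.19 across peaks, which are not independent, where the shared C libraries alone gave 0.51 to 0.52. Changes in 1 group alone lower r, and the simulated groups were unchanged, so the lower r does not show less in common. The covariance was 0.15 against 0.07 in simulation. The simulated C libraries had the spread fitted over all groups. The root mean square log2 difference between replicates was 0.63 in C and 0.30 in P320. The simulated covariance may thus be too low, and the excess over it was not shown to go beyond the shared C libraries. The 3308 peaks changed alike were 2073 without C replicate 2, 1498 without P320 replicate 1, 1461 without P320 replicate 2 and 5884 when scaled on gene-end peaks. Peaks gained in both ran from 211 with that scaling to 1828 without C replicate 1 and 2728 on adjusted p alone, peaks lost in both from 814 without P320 replicate 2 to 5673 with that scaling. Opposite calls numbered 3354 with that scaling, 865 with the window offset, 553 without C replicate 1 and 489 and 511 without P320 replicates 1 and 2.

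Peaks of whole 5 Mb windows moved together in the adapted populations. Of 561 windows with at least 30 peaks, the median log2 fold change reached 0.5 in absolute value in 24 windows in T5, 74 in T10, 124 in T40 and 138 in T320, 65 raised and 73 lowered. The median over the windows of chromosome 1 was -0.26 in T5, -0.55 in T10, -0.76 in T40 and -0.72 in T320, and that of chromosome 14 was 0.69 in T40 and 0.15 in T320. On chromosome 1 lie CTPS1 and PARP1. Window values of T80 and T320 had r = 0.91 across windows, and those of P320 and T320 r = 0.07. P10 had 68 shifted windows, 64 of them lowered, and P320 21, 20 of them lowered. Window values followed the share of gene-end peaks in a window in P10 and P320, with a rank correlation across windows of 0.69 and 0.78, against -0.02 in T320, so the window offset does not measure the same thing in P as in T.

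**Figure D4:**
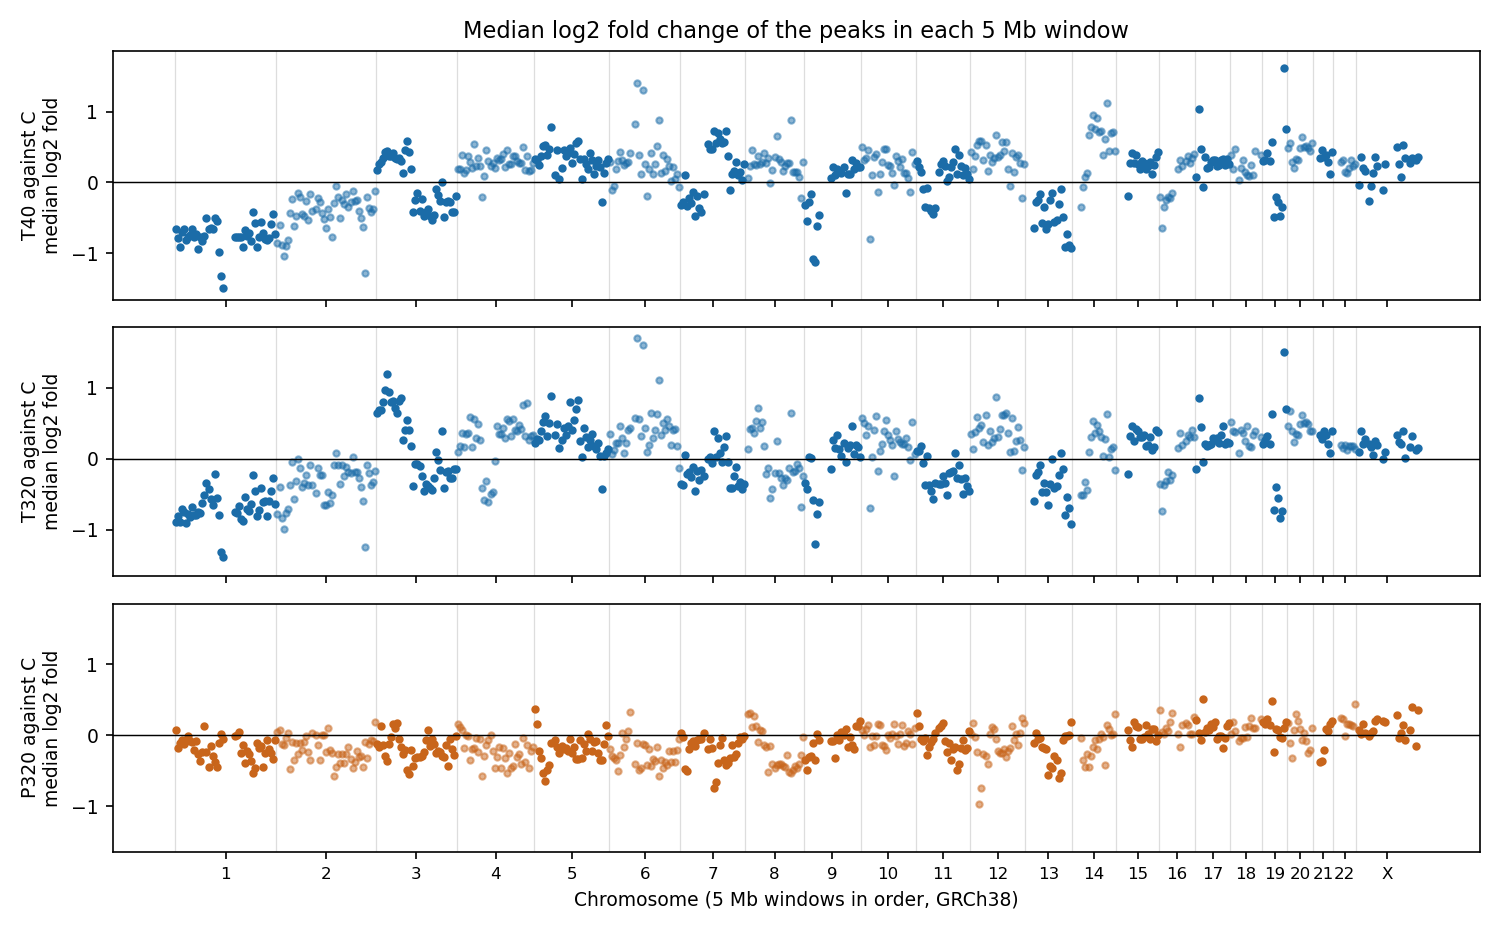
Median log2 fold change against C of the peaks of each 5 Mb window (y axis; windows with at least 30 peaks along the genome on the x axis, alternate chromosomes paler) in T40, T320 and P320. Windows shifted by at least 0.5 numbered 124 in T40, 138 in T320 and 21 in P320.

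The loss at CDKN2A and CDKN2B extended beyond both genes, a region examined after their values were seen. In T320 and T40, 15 consecutive peaks with at least 2 CPM in C, from 21863349 to 22119830 on chromosome 9 and including peaks inside MTAP, a gene of methionine salvage, were at an eighth of C or less. Their sum was 2.36% and 0.28% of C in the 2 T320 libraries and 0.67% and 0.46% in T40. It was 51.4% and 61.7% in T5, 33.4% and 31.8% in T10, 17.2% and 5.66% in T20, 8.84% and 6.97% in T80 and 22.5% and 26.0% in T160. In P10 it was 97.7% and 97.7%, in P320 102.8% and 97.0%, and in C itself 86.0% and 114.0%.

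**Figure D5:**
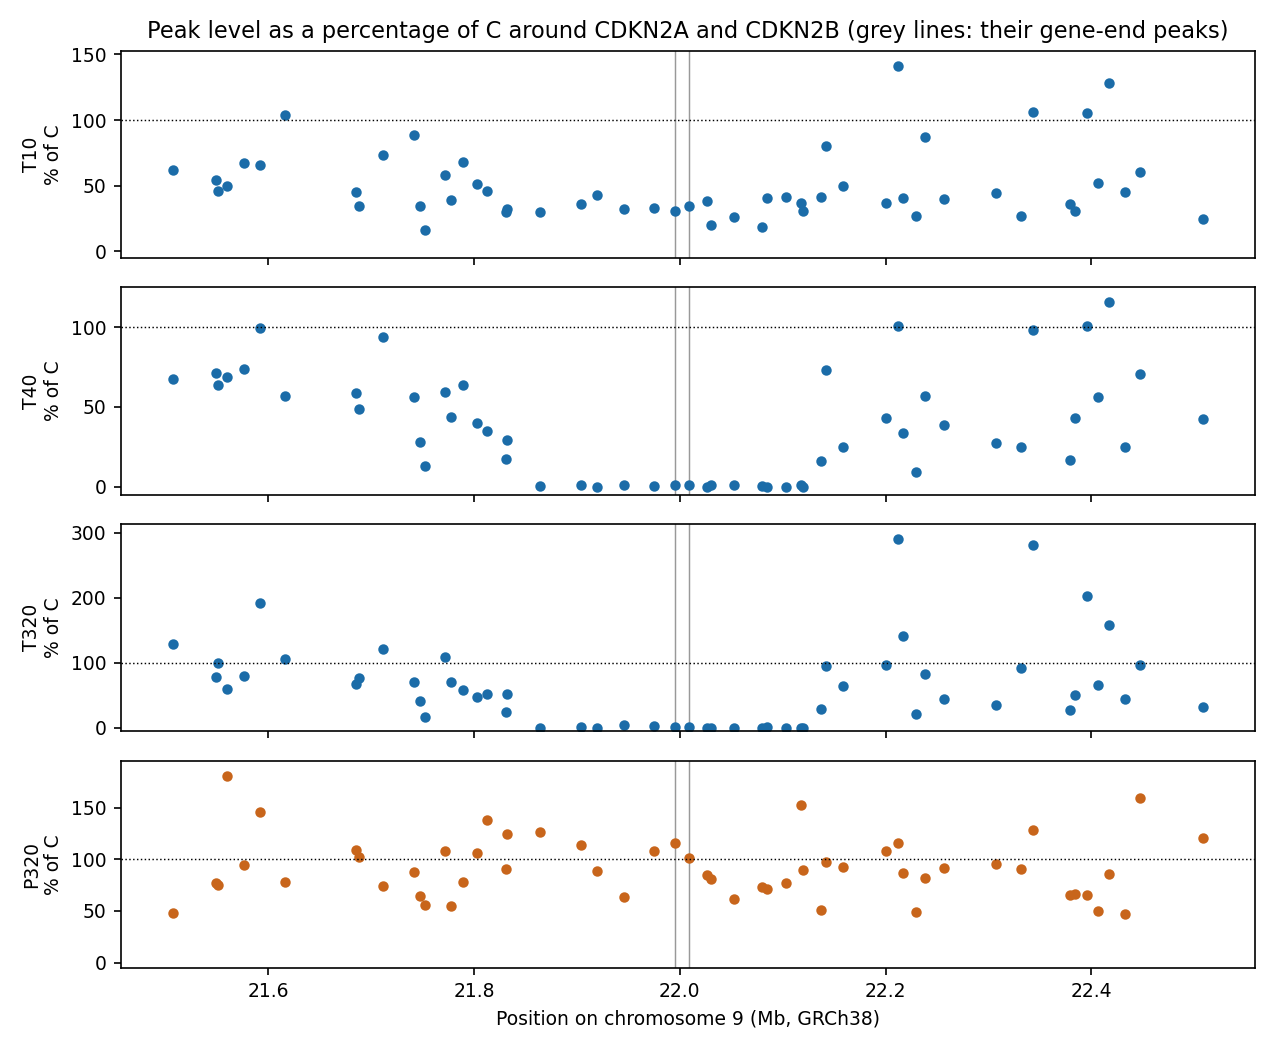
Accessibility of each peak around CDKN2A and CDKN2B as a percentage of C (y axis, scales differ between panels) by position on chromosome 9 (x axis, GRCh38) in T10, T40, T320 and P320. From 21863349 to 22119830 the sum of 15 peaks was at most 2.36% of C in the T40 and T320 libraries and at least 97.0% in the P320 libraries.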

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

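The contrast of dose effects, the comparison of library depths, the permuted dose orders and the tests of the segment around CDKN2A were chosen only after the result each concerns had been seen; the other tests were fixed before. The result below stood out by a difference between groups, measured by a test of the difference itself. The change from T10 to T320 differed from the change from P10 to P320 at 24764 peaks, 14264 higher and 10500 lower (edgeR), at 57.6% higher, or 83.0% when scaled on gene-end peaks, which raised the median by 0.43. As an example chosen after its values were seen, the CXCL1 peak was at 6.71 CPM in T10, 2.59 CPM in T320, 14.4 CPM in P10 and 1.04 CPM in P320.

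Peaks of whole 5 Mb windows shifted together between T320 and C, for which a change in DNA copy number is a candidate explanation. In 153 shifted windows of 533 tested, peaks near gene ends moved by 0.844 times the shift of distal peaks left out of the choice of windows (95% bootstrap interval 0.735 to 0.944), with the same sign in 152. This meets the bound of 0.7 set beforehand for that explanation, but the interval lies below 1, so gene-end peaks shifted less than a change in copy number alone would give. Copy number change of whole 5 Mb windows as the only cause of the calls in T320 is argued against. With the window offset 69.9% of the calls kept their direction. That offset leaves copy number changes narrower than 5 Mb in place, so it cannot decide on those. A change of chromatin over megabases could give such a ratio too, and DNA was not measured here, so both stay open for the windows, as does adaptation itself, which was not tested apart from them.

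More peaks were called against C in P10 (23217) than in P320 (12447), and 66.8% of those in P320 were lost, but scaling on gene-end peaks turned the order (21784 against 24253), it was 12799 against 11236 without C replicate 2, and without either P320 library 52.6% and 53.7% were gained. Unequal signal to background, as far as a trended offset removes it, is argued against as the source of the order, since with it P10 still had 2.16 times the calls of P320, though the turn under gene-end scaling leaves other effects of scaling open. Greater depth is argued against by the mean total count of P10, 0.774 times that of P320. For the losses in P320 the trended offset gave 57.8% lost, between the bounds set beforehand, so unequal signal to background and the drug cannot be told apart there, the P320 libraries holding 38.2% and 37.5% of counts in gene-end peaks. The dose stays open and was not tested separately.

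Peaks of CDKN2A and CDKN2B were near 0 CPM in T40 and T320, and a deletion of the surrounding segment is a candidate explanation. All 9 of the 9 peaks within 100 kb that lie outside both genes and held at least 2 CPM in C were at an eighth of C or less in T320 (100%), as a deletion needs. The nearest peaks outside with at least 2 CPM in C, which end at 21832665 and start at 22136489 on chromosome 9 (GRCh38), were at 52.7% and 29.4% of C, and no other run of at least 5 peaks that low was found in T320. The partial levels in T5, T10, T20, T80 and T160 might come from a mixture of cells with and without the segment, which was not tested. After 0.67% and 0.46% of C in the T40 libraries, the segment was at 8.84% and 6.97% in T80. It was at 22.5% and 26.0% in T160 and at 2.36% and 0.28% in T320. A deletion in all T40 cells, passed on from them to T80 and T160, could not give this return. How the populations descend from each other was not examined. Closing of the chromatin over the segment is the other explanation. Of 105048 peaks, only 14 and 32 held 0 counts in T320 replicates 1 and 2, though 16299 were called lost. Segment peaks at 22079450 and 22103192, at 16.3 and 18.2 CPM in C, were at 0 CPM in both libraries. Lost peaks elsewhere thus rarely reached 0, which argues against closing alone in T320. DNA was not measured here, so a deletion was not shown directly.

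For the dose trend of 6005 peaks, 1 of 41 orders of the 7 doses, the real one, gave as many calls. The highest of the other 40 gave 0, which argues against a chance order. Their lowest adjusted p (edgeR) was 0.057, just over the cut of 0.05, so the count of 0 depends on that cut. The reverse of the real order, which would mirror its slopes, was left out of the draw. Anything else that differed along the same order of populations would pass too, so dose itself was not tested apart. At an unadjusted p under 0.05 the real order gave 30366 peaks and the highest other 21623. DESeq2 called 6931 peaks for the real order and was not run on the others.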

How the results depend on the processing

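Chosen only after the data were seen were the window offset with the replicate block, the filter for the trend, the omissions and gene-end scaling in the overlap and named peaks, the simulated depths, and all tests of the contrast of dose effects. The cause of each change below was not tested, except that omitting a library leaves fewer samples and dropping the fold or slope minimum adds peaks. Not run were the GC offset, alone or with the block, the motif tests and the comparisons of the 8 other T320 samples. Depth limited detection of a 4-fold change in simulated data, found at 151 of 200 peaks at 0.5 times the depth, 169 at the real depth and 179 at 2 times the depth, and at a 2-fold change 51, 48 and 57 of 200 were found.

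Totals of T against C, P10 against C, P320 against P10, T10 against P10 and T320 against P320, though not their gains and losses, stayed within 1.5 times unless a library was omitted. P320 against C gave 24253 with TMM from gene-end peaks and 19961 with no fold minimum. T10 against T5 gave 5798 with the replicate block and 2146 with the window offset. T20 against T10 gave 895 with the trended offset, 1710 with the block, 188 with the window offset, 981 with window offset and block, and 1152 with DESeq2. T40 against T20, 0 in the edgeR fit reported, gave 4 with the trended offset, 1 with TMM from gene-end peaks, 7 with the block, 11 with window offset and block, 42 with DESeq2 and 2 in a fit of only the groups compared (5906 at an unadjusted p under 0.05). T80 against T40, also 0, gave 5 with window offset and block and 8 with DESeq2 (4180 unadjusted). T160 against T80, also 0, gave 11 with total count scaling, 61 with the trended offset, 45 with TMM from gene-end peaks, 161 with the block, 81 with window offset and block, 143 with DESeq2 and 129 in a fit of only the groups compared (8113 unadjusted). T320 against T160 gave 6447 with the block and 6129 with no fold minimum. The dose trend gave 11423 with no slope minimum, and the overlap of acute and adapted changes 6780 on adjusted p alone and 5884 with TMM from gene-end peaks.

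Leaving out a library gave ranges of 2831 (without T5 replicate 2) to 10289 for T5 against C, 10005 (without T10 replicate 2) to 19280 for T10 against C, 15999 (without T20 replicate 2) to 27259 for T20 against C, 12799 (without C replicate 2) to 26909 for P10 against C, 6511 (without P320 replicate 1) to 11786 for P320 against C, 5725 (without P320 replicate 1) to 7729 for P320 against P10, 22799 (without T10 replicate 2) to 37350 for T10 against P10, 412 (without T5 replicate 2) to 2625 for T10 against T5, 2 (without T20 replicate 2) to 520 for T20 against T10, 0 to 2 (without T20 replicate 2) for T40 against T20, and 281 (without T160 replicate 2) to 5161 for T320 against T160. The dose trend ran from 1673 (without T320) to 9154 (without T160), and the overlap from 1461 (without P320 replicate 2) to 4755. The other libraries that moved a count over 1.5 times were C replicate 2 (4186) and T5 replicate 1 (6124) for T5 against C, P10 replicate 2 (15416) for P10 against C, P320 replicate 2 (6564) for P320 against C, P10 replicates 1 (7729) and 2 (7384) and P320 replicate 2 (6884) for P320 against P10, T5 replicate 1 (2010) and T10 replicate 2 (706) for T10 against T5, T10 replicates 1 (129) and 2 (12) for T20 against T10, T40 replicate 1 (1) for T40 against T20, T160 replicate 1 (2693) and T320 replicate 2 (393) for T320 against T160, replicate 2 of all populations (3806, against 6079 without replicate 1) for the trend, and C replicate 2 (2073) and P320 replicate 1 (1498) for the overlap.

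Directions turned, for no called peak, as follows. The peak of PARP1, T320 against C had 0.02153 with the window offset, and the peak of PARP1, dose trend 0.051. The peak of BRCA2, P320 against C had -0.01423 with total count scaling -0.1776 with the trended offset and -0.4208 with TMM from gene-end peaks, and ran from -0.142 (without C replicate 1) to 0.2915 over omitted libraries. The peak of BRCA2, dose trend had 0.01162 with the window offset and 0.0003061 without T5, with a range from -0.05858 to 0.0003061 over omissions, at 0.0002695 without replicate 1. The peak of CD44, T320 against P320 had 0.1846 with the window offset and 0.1414 with TMM from gene-end peaks, with which the peak of SLFN11, P320 against C had -0.2328. The peak of SLFN11, dose trend had -0.003933 without T5, its range being -0.003933 to 0.1252, and the peak of CD24, T320 against C ran from -0.2672 to 0.2571 (without C replicate 2). With fry, which tests the list alone, some directions turned in every comparison with lists. Those with a fry adjusted p under 0.05 were epithelial (6.949e-05), antigen presentation and cell cycle (0.03762 each) in P320 against C, AP-1 and immediate early (0.02029) and Wnt and stemness (0.0006538) in T320 against P320, and epithelial (0.018) in P320 against P10, where the called mesenchymal list also turned (0.48). The position of P320 along the C to T320 axis was -0.0324 on gained peaks alone.

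Of 279 named values the window offset ended 48 calls and made 2, TMM from gene-end peaks ended 49, the trended offset ended 19 and total count scaling 11, and DESeq2 ended 1 and made 1. Apart from the counts above, the replicate block, run for the trend on 14 libraries, ended 1 call of a named peak, OLIG2 (0.2395), and those of the list glycolysis and hypoxia, dose trend (0.05428) and the list neural markers, dose trend (0.06991), and changed no other call it was run on (the added list tests were not). For the 88 list tests of the 3 main comparisons and the trend an estimated correlation ended 8 calls, peaks nearest to the gene ended 5 and made 12, the window offset ended 1 and made 6, total count scaling made 1, the trended offset ended 2 and made 1, and fry ended 2 and made 25. In the added list tests an estimated correlation ended 6 calls and the window offset 2, all in P320 against P10, and that offset made 1 each in T5 and P10. TMM from gene-end peaks moved the median of all peaks by over 0.1 log2 units in T10 (-0.13), T20 (-0.17), T40 (-0.19), T80 (-0.18), T160 (-0.14), P10 (-0.15) and P320 (-0.49) against C, P320 against P10 (-0.34), T10 against T5 (-0.20) and T320 against P320 (0.44), the window offset in T20 (-0.11), T40 (-0.15) and T80 (-0.10) against C, and the trended offset in P320 against C (0.13) and T10 against P10 (-0.11).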

Other observations

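The scan of consecutive peaks and the lists in P10 were chosen only after the data had been seen. Runs of at least 5 consecutive peaks at 4 times C or more numbered 0 in T5, 1 in T10, 19 in T20, 18 in T40, 20 in T80, 9 in T160 and 36 in T320. On chromosome 19, 8 peaks from 52922603 to 53038363 (GRCh38), over the zinc-finger gene ZNF816 and the endogenous retroviral gene ERVV-1, averaged 6.42 CPM in C and 41.2 CPM in T320, and 8 peaks from 53057911 to 53197656, over ZNF160, ZNF415, ZNF347 and ZNF665, averaged 4.98 CPM in C and 36.6 CPM in T320. On chromosome 16, 2 runs of 9 and 6 peaks lay in CDH13, a cadherin without a transmembrane part, at 1.32 CPM and 1.11 CPM in C and 10.9 CPM and 9.81 CPM in T320. A run of 8 peaks on chromosome 3 from 165800786 to 166305241 took in BCHE, which encodes butyrylcholinesterase, at 1.81 CPM in C and 12.5 CPM in T320. The single run in P320 held 5 peaks on chromosome 16 from 87789562 to 87829595, beside SLC7A5, at 4.07 CPM in C and 22.9 CPM in P320, and P10 had 0.

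In P10 against C mesenchymal genes had 5 gains of 31 (adjusted p = 0.24), FN1, TWIST2, COL6A2, TGFB1 and ITGB3, and the AP-1 list 5 gains and 2 losses of 21 (0.42), the losses being FOS and EGR1. Endothelial markers had 3 gains of 9 (0.42), ERG, CLDN5 and SOX18, and homologous recombination and PARP 0 calls of 34 with edgeR (0.24). Scaled on gene-end peaks the gains were 2, 4 and 1 in the first 3 lists. Distal losses in P320 against C included 2 peaks inside SOX5, a transcription factor, on chromosome 12, from 38.3 ± 1.2 to 9.68 ± 0.66 CPM (-1.98 ± 0.19) at 23553314 and from 141 to 33.7 ± 2.6 CPM (-2.07 ± 0.19) at 24113597. Distal gains in T320 against P320 included a peak inside AHNAK, at 1.18 ± 0.17 CPM in P320 (4.29 ± 0.26), and distal losses in T320 against C a peak inside MOB3B, at 43.7 ± 6.4 CPM in C and 3.64 ± 0.90 CPM in T320.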
